A study of Rattus norvegicus with 6 samples.

How the data were processed

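Mononuclear cells of the right gastrocnemius of male F344/BN rats were profiled in 6 libraries, 1 for each combination of 2 ages (adult, old) and 3 conditions (ambulation, 7 days of recovery after 14 days of hindlimb suspension, and recovery with 4 bouts of mechanotherapy). Per the labels' protocols, muscles were digested with collagenase II and dispase, live cells negative for propidium iodide were loaded on the 10x 3' kit with version 3.0 chemistry, and libraries were sequenced on HiSeq instruments. The deposited matrices hold UMI counts per gene and barcode, which the authors made with Cell Ranger 4.0.0, per the submitters' processing notes. The genome build and annotation are not given in the sources used here. Each matrix had 25399 genes, named by symbol and Ensembl identifier as in the files; no genomic coordinates were used. Of the list members fixed beforehand, Col1a2 was not analysed here. Which barcodes the authors kept as cells shapes every share below, and dissociation and live sorting favour cells that survive both, so that shares of these cells are not shares of the tissue. Droplets with sarcomeric transcripts can hold myofibre fragments or RNA rather than mononuclear cells.

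Groups were taken from the labels. The flow cell and lane of each library came from the labels too: both ambulation libraries carried the same flow cell and lane, and the recovery and mechanotherapy libraries of an age carried the same lane of another flow cell. The files held 10084, 17021 and 16197 barcodes in the adult ambulation, recovery and mechanotherapy libraries and 10515, 11056 and 18027 in the old ones, 82900 in all. Cells with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs were kept. Doublets were scored with Scrublet as in scanpy 1.11.5, and the highest-scoring barcodes were left out, as many as 0.8% per 1000 barcodes of the library: 813, 2318 and 2099 adult and 885, 978 and 2600 old barcodes. A fixed fraction was used because the caller's own threshold marked 1 barcode of the old recovery library; over the libraries in the same order it marked 449, 1408, 1323, 316, 1 and 1047. This left 69750 cells. Counts scaled to 10000 per cell and log-transformed gave 2000 variable genes, 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1.0, over all libraries together and without batch correction; clusters under 20 cells were not named.

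Clusters were named from marker genes fixed before the data were examined. A marker counted as detected in a cluster at 2-fold or more over the median cluster (with 10 CPM added) and in at least 10% of its cells, and a name needed 3 detected markers and could not go against the 10 leading genes by fold. This rule was refined after the clusters were seen; the markers were not. The 6 clusters it left unnamed were led by Csrp3 and Ankrd1 (cluster 17), RT1-Da and RT1-Db1 (18), Cxcl14 and Smoc2 (22), Apod and Hbb (24), Stmn1 and Top2a (28), and RT1-Da and Cd74 (31). Interleukin, chemokine or stress genes lead some named clusters, as Il6, Cxcl3 and Ptgs2 do for cluster 0 and Fos for cluster 4.

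UMIs were summed per library and class and scaled to that sum as CPM, the usual unit of counts per fixed total. Classes with at least 50 cells in both libraries, 7 in all, were compared gene by gene. A fold is the ratio of CPM, with an exact conditional binomial 95% interval. Shares have exact Clopper-Pearson 95% intervals. Both cover counting error only. A fold against 0 UMIs used a floor of 3 counts over the class sum and is given as at least that size. Log2 ratios of such genes, also under the alternatives, are bounds of the same kind. The 7 comparisons were mechanotherapy over recovery and recovery over ambulation at each age, and old over adult in each condition. Cells are not replicates, and with 1 library per group no test was made. Precision follows depth: kept cells had a median of 2745, 2950 and 3438 UMIs in the adult and 3166, 4203 and 3161 in the old libraries.

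For 33 gene lists fixed before the data were examined, the members with at least 20 UMIs in the 2 class sums were measured, and those at least 1.5-fold higher or lower with the interval on that side of 1 were counted. The list's median log2 ratio, less the median of all genes, was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The lists were fibrillar collagens, other collagens, basement membrane, small leucine-rich proteoglycans, matricellular proteins, elastic fibre and fibronectin, collagen processing and cross-linking, matrix proteases, protease inhibitors, hyaluronan and versican, integrins and matrix receptors; TGF-beta family and targets, mechanoresponsive and YAP/TAZ targets, myofibroblast, growth factors and chemokines of stroma, complement, resident macrophage, inflammatory macrophage, lipid-handling and repair macrophage, MHC class II, interferon response, cell cycle; dissociation and immediate-early, heat shock, senescence, endothelial angiogenic and tip cell, endothelial lipid and capillary, satellite cell quiescence, myogenic activation and differentiation, fibro-adipogenic subset and adipogenesis, oxidative phosphorylation, nuclear genes, glycolysis; and iron and oxidative stress. Named genes followed a rule fixed before the data were examined: genes with a symbol that were not mitochondrial, ribosomal protein, haemoglobin or marker genes, with at least 30 UMIs in the library of higher CPM and a CPM there at least 25% of the highest in any class, ranked by the interval bound nearest 1; the 5 highest and lowest in fibroblast-like, 4 in macrophage-like and 3 in endothelial-like cells, per comparison except age in mechanotherapy. The 5 fibroblast-like genes per direction with the largest smaller bound at both ages of mechanotherapy were added, and up to 4 members of each list discussed. Some of the genes this rule takes are not reported here. Correlations across genes used genes with at least 50 UMIs in each comparison. Ligand-receptor sums used 87 fixed pairs with at least 10 CPM of both genes in 1 of the 2 libraries. The number of correlations was 21, over 7 classes and 3 pairs of comparisons that share no library.

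The fold and list code was tested on counts simulated from the class sums, with counting error only and known folds for 200 genes. For mechanotherapy in adult fibroblast-like cells (10802 genes), 96%, 100% and 0.620% of genes changed 2-fold, 4-fold and not at all passed the size rule. In old macrophage-like cells (5447 genes) the shares were 89%, 100% and 1.62%. These are not rates of false calls here.

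The alternatives tried were no doublets left out, at most 10% mitochondrial UMIs, at least 1000 UMIs and 500 genes, resolution 0.5, 1000 variable genes with 20 components, shares without immune- and erythroid-like cells, CPM without mitochondrial and ribosomal protein genes, scaling by the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3, the mean of each cell's own CPM, each cell thinned to 1000 UMIs (shallower cells, 551, 787 and 721 adult and 475, 375 and 1706 old, left out), list members with at least 100 UMIs or with any UMI and a pseudocount of 1, correlations over at least 200 UMIs and pairs at 50 CPM. Weighting the fibroblast-like clusters alike and shares without myofibre-like cells were added after seeing the data. Which results are treated as the leading ones of each comparison was also settled after they were seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.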

Results

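Single-cell transcriptomes were read from mononuclear cells of the right gastrocnemius, a calf muscle, of male rats of the hybrid strain F344/BN. The tissue was dissociated with collagenase II and dispase. Live cells that excluded propidium iodide were loaded for 10x 3' sequencing, in which each captured transcript carries a unique molecular identifier (UMI). The 6 libraries crossed 2 ages, adult and old, with 3 conditions, called here ambulation (WB, normal ambulation), recovery (RE, 7 days of recovery after 14 days of disuse by hindlimb suspension) and mechanotherapy (REM, the same recovery with a 4.5 N load applied at 0.5 Hz for 30 min in 4 bouts). The design asks how expression of extracellular matrix genes in these cells differs with age during recovery and with mechanotherapy. Each group was 1 library without replicates, and the number of rats behind each library is not given in the sources used here. No test was therefore made. The values describe these libraries. Square brackets after a share or a fold hold 95% intervals that cover counting error only. The files held between 10084 and 18027 barcodes and between 31598766 and 67557537 UMIs per library. Filtering left 9159, 13924 and 13286 cells in the adult ambulation, recovery and mechanotherapy libraries and 9391, 9717 and 14273 in the old ones. Their median lay between 2745 and 4203 UMIs per cell. Both ambulation libraries were run on another flow cell than the recovery and mechanotherapy libraries, so recovery and flow cell cannot be told apart. Old and adult libraries of the recovery and mechanotherapy conditions were run on different lanes, which leaves age and lane confounded there. Mechanotherapy, and age in ambulation, were compared within 1 lane.

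Among the live-gated cells, fibroblast-like cells were the most numerous class, at 52.4% [51.4 to 53.4], 46.2% [45.4 to 47.0] and 57.6% [56.8 to 58.4] of kept cells in the adult ambulation, recovery and mechanotherapy libraries and 40.0% [39.0 to 41.0], 64.3% [63.3 to 65.2] and 45.1% [44.3 to 46.0] in the old ones. Droplets with sarcomeric transcripts, called myofibre-like, ranged from 4.02% in the old recovery library to 28.9% in the adult recovery library. Cells named macrophage- or monocyte-like (macrophage-like for short) made up 3.75%, 6.59% and 9.30% in the adult and 3.49%, 5.03% and 4.05% in the old libraries, in the same order of conditions. Endothelial-like cells made up 3.41%, 3.89% and 4.47% in the adult and 3.05%, 4.6% and 8.77% in the old libraries. T- or NK-like cells were a larger share of each old library than of its adult counterpart, 2.76-fold [2.43 to 3.15] in ambulation, 3.52-fold [3.04 to 4.07] in recovery and 1.97-fold [1.68 to 2.30] in mechanotherapy. Of 33 clusters 27 were named. The 6 unnamed clusters held 3.75%, 5.19% and 4.57% of the adult libraries and 10.9%, 5.09% and 9.54% of the old ones. The 8 fibroblast-like clusters were unevenly filled. Cluster 0, led by Smoc2, Tnfaip6, Has1, Cilp and Il6, held 1.90%, 2.41% and 6.26% of this class in the adult libraries but 6.04%, 54.9% and 38.8% in the old ones. Cluster 4, with Cxcl14, Ogn and Fos among its leading genes, held 27.3%, 15.8% and 16.1% against 13.2%, 0.929% and 6.69%. Cluster 12, led by Cilp, Thbs4, Smoc2 and Ccn2, held 3.90%, 10.1% and 5.24% against 17.6%, 3.51% and 4.27%. Cluster 3, led in part by Fbn1 and Igfbp5, held 22.1%, 17.4% and 14.3% against 13.5%, 4.39% and 9.76%. Cluster 6, led in part by Col1a1, held 13.2%, 8.98% and 12.2% against 11.0%, 13.9% and 12.4%. Values of these genes over the whole class move with this makeup. Several genes described further on also served to name the classes, among them Col1a1, Col3a1, Dcn, Thbs4, Comp, Fmod, Lyve1, Cd163, Vcam1 and Myog.

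**Figure D1:**
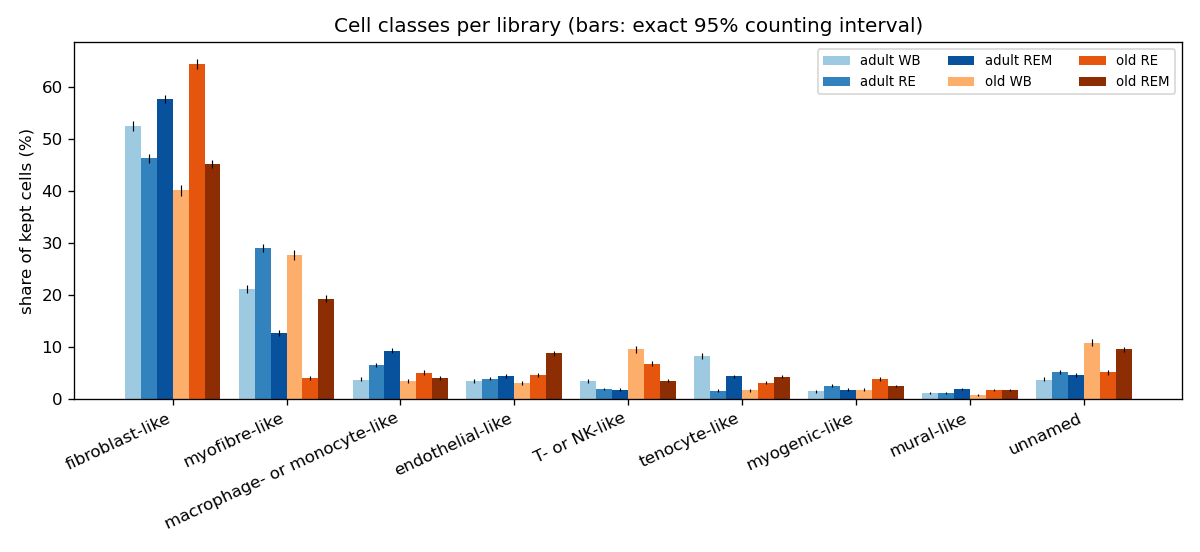
Share of kept cells (%) of each cell class in the 6 libraries, as bars with exact 95% counting intervals. Fibroblast-like cells range from 40.0% in the old ambulation library to 64.3% in the old recovery library.

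Mechanotherapy in adult rats was read from the adult mechanotherapy library beside the adult recovery library. Heat shock genes stood higher in its fibroblast-like cells. Hsph1 (ENSRNOG00000000902), a co-chaperone, was 3.76-fold [3.63 to 3.89] higher, Hspb1 (ENSRNOG00000023546), a small heat shock protein, 2.79-fold [2.75 to 2.82], and Hspa1b (ENSRNOG00000050647), an inducible chaperone, 2.75-fold [2.73 to 2.77]. The heat shock list had 9 of 11 measured members higher and 0 lower, by a rule of size (at least 1.5-fold, with the counting interval on that side of 1) that is not a test. Its median log2 ratio, relative to the median of all genes, as are the other list medians given with a percentile, was 1.35 (percentile 100 of 10000 random lists matched on expression). Il1rl1 (ENSRNOG00000014835), the receptor of the alarmin encoded by Il33, was 4.82-fold [3.20 to 7.53] higher over 61 cells with a UMI, and Crabp2 (ENSRNOG00000022101), a retinoic acid-binding protein, 3.35-fold [2.85 to 3.97]. Sult1e1 (ENSRNOG00000001957), an oestrogen sulfotransferase, was at least 28.4-fold lower with UMIs in 9 cells. The meiotic genes Rec114 (ENSRNOG00000009332) and Syce1 (ENSRNOG00000024073) were at least 23.0-fold and 6.65-fold [3.78 to 12.5] lower. Duox1 (ENSRNOG00000033348), a peroxide-generating oxidase, was 3.21-fold [2.15 to 4.88] lower. Among matrix genes, the fibrillar collagens list had 0 of 6 higher and 1 lower. Its main members Col1a1 (ENSRNOG00000003897) and Col3a1 (ENSRNOG00000003357) were 1.33-fold [1.32 to 1.35] and 1.32-fold [1.31 to 1.33] higher, short of that size. Of elastic fibre and fibronectin genes, 3 of 15 measured members were lower and 0 higher, led by Ltbp2 (ENSRNOG00000012094), a latent TGF-beta-binding protein, at 2.31-fold [1.78 to 3.02] and the microfibril gene Mfap4 (ENSRNOG00000002382) at 1.75-fold [1.60 to 1.92]. Thrombospondin gene Thbs4 (ENSRNOG00000012471) was 2.25-fold [2.20 to 2.31] lower and Fmod (ENSRNOG00000003183), a collagen-binding proteoglycan, 2.33-fold [1.99 to 2.74]. Matricellular proteins had 0 of 20 higher and 2 lower (1 and 1 with TMM scaling), and small leucine-rich proteoglycans 1 of 8 higher and 1 lower. Timp1 (ENSRNOG00000010208), an inhibitor of metalloproteinases, was 1.64-fold [1.62 to 1.65] higher. The median of all genes lay at a log2 ratio of −0.12. Thinning each cell to 1000 UMIs moved log2 ratios to a bound of −2.13 for Sult1e1, to a bound of −2.75 for Rec114 and from −2.73 to −3.34 for Syce1.

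In old rats, the mechanotherapy library beside the recovery library held more Col1a1 and Col3a1 transcripts in fibroblast-like cells. Col1a1 was 2.63-fold [2.59 to 2.67] higher and Col3a1 1.71-fold [1.69 to 1.74]. The fibrillar collagens list had 3 of 6 higher and 1 lower. The matrix genes Sparc (ENSRNOG00000012840), a collagen-binding matricellular protein, and Eln (ENSRNOG00000001469), elastin, were 1.95-fold [1.92 to 1.98] and 2.65-fold [2.44 to 2.88] higher. Lower were Tnc (ENSRNOG00000058645), tenascin C, at 3.95-fold [3.5 to 4.47], Thbs1 (ENSRNOG00000045829) at 2.23-fold [2.08 to 2.39], Ltbp2 at 2.91-fold [2.46 to 3.44], the aggrecanase Adamts9 (ENSRNOG00000023257) at 2.85-fold [2.52 to 3.23] and Timp1 at 1.64-fold [1.63 to 1.65]. Of the hyaluronan and versican list, 4 of 9 measured members were lower and 0 higher, among them the hyaluronan receptor Cd44 (ENSRNOG00000006094) at 1.60-fold [1.55 to 1.66] and Vcan (ENSRNOG00000029212), versican, at 1.56-fold [1.53 to 1.59]. Its median was −0.65 (percentile 0.0900). Matrix proteases had 2 of 24 higher and 4 lower (1 and 5 with TMM scaling), and matricellular proteins 2 of 20 higher and 3 lower. Immediate-early transcription factors were higher. Fos (ENSRNOG00000008015), a leading gene of cluster 4, stood 3.62-fold [3.55 to 3.70] higher and Btg2 (ENSRNOG00000003300), an antiproliferative gene, 2.82-fold [2.77 to 2.88]. The dissociation and immediate-early list had 10 of 19 higher and 0 lower. With the fibroblast-like clusters weighted alike in both libraries, an alternative chosen after seeing the data, 4 members were higher. Also higher were Dmkn (ENSRNOG00000055934), a secreted dermokine, at 4.09-fold [3.21 to 5.25], Stmn4 (ENSRNOG00000053334), a microtubule regulator, at 3.60-fold [3.04 to 4.28] and Dnajb1 (ENSRNOG00000021824), a co-chaperone, at 2.82-fold [2.76 to 2.89]. The heat shock list had 4 of 11 higher and 0 lower. Bdnf (ENSRNOG00000047466), a neurotrophin, was 5.60-fold [3.93 to 8.20] lower, Pop1 (ENSRNOG00000005243), a subunit of RNA-processing ribonucleases, 4.35-fold [3.37 to 5.68], Riox1 (ENSRNOG00000010126), a ribosomal oxygenase, 3.64-fold [2.99 to 4.46] and Sfrp5 (ENSRNOG00000014940), a secreted Wnt antagonist, 7.96-fold [4.13 to 17.2] over 20 cells. Igh-6 (ENSRNOG00000048402), an immunoglobulin heavy chain, was 5258-fold [943 to 207720] lower, with UMIs in 8 cells and 61.8% of them in 1 cell. MHC class II genes had 5 of 5 higher and 0 lower. Cd74 (ENSRNOG00000018735) reached 19.1 CPM (UMIs scaled to a fixed total per class) in these cells against 15420 CPM in macrophage-like cells. The median of all genes lay at a log2 ratio of 0.10. Weighting the fibroblast-like clusters alike moved log2 ratios from 1.86 to 0.50 for Fos, from 2.03 to 0.93 for Dmkn and from 1.85 to 1.09 for Stmn4. Thinned to 1000 UMIs per cell, log2 ratios went from −2.99 to −0.78 for Sfrp5, from −2.49 to −1.52 for Bdnf and from −12.36 to −7.10 for Igh-6.

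Higher in fibroblast-like cells of both mechanotherapy libraries, adult and old, were Dnajb1 (2.78-fold and 2.82-fold), Hsph1 (3.76-fold and 2.07-fold), Hspa1b (2.75-fold and 1.68-fold), the co-chaperone Bag3 (ENSRNOG00000020298) (2.15-fold and 1.64-fold) and the secreted serine protease Htra1 (ENSRNOG00000020533) (1.55-fold and 1.54-fold). Lower in both were Cilp (ENSRNOG00000029911), a cartilage matrix protein that leads clusters 0 and 12 (1.90-fold and 1.81-fold), the histone methyltransferase Suv39h2 (ENSRNOG00000015585) (1.82-fold and 2.32-fold), the antiviral gene Zc3hav1 (ENSRNOG00000013948) (1.44-fold and 1.46-fold), the mitochondrial phosphodiesterase Pde12 (ENSRNOG00000059442) (1.62-fold and 1.65-fold) and Igfbp3 (ENSRNOG00000061910), an IGF-binding protein (1.40-fold and 1.94-fold). Heat shock genes were higher in the other classes too: 11 of 11 (adult) and 5 of 11 (old) members in macrophage-like, 7 of 11 (adult) and 5 of 11 (old) members in endothelial-like, 10 of 11 (adult) and 7 of 11 (old) members in myogenic-like, 8 of 11 (adult) and 5 of 11 (old) members in mural-like, 7 of 11 (adult) and 6 of 11 (old) members in tenocyte-like and 10 of 11 (adult) and 4 of 11 (old) members in T- or NK-like cells. Across genes, which are not independent replicates, the log2 ratios of mechanotherapy in adult and old fibroblast-like cells had a Pearson r of −0.12 and a Spearman rho of −0.088 over 10439 genes. By size alone, 68 of 209 genes past 1.5-fold at both ages shared a direction. In macrophage-like cells r was 0.182 and rho 0.22, with 224 of 335 genes in a shared direction. In endothelial-like cells r was 0.111 and rho 0.108, with 89 of 126. There r was −0.039 with doublets kept, 0.283 with thinned cells and 0.244 over genes with at least 200 UMIs. In macrophage-like cells r was 0.33 with at most 10% mitochondrial UMIs and 0.32 over genes with at least 200 UMIs. The fibroblast-like share was 1.247-fold [1.21 to 1.29] higher in the adult mechanotherapy library but 1.42-fold [1.37 to 1.47] lower in the old one. The myofibre-like share was 2.28-fold [2.15 to 2.41] lower and 4.78-fold [4.30 to 5.33] higher. As a share of cells that were not myofibre-like, fibroblast-like cells had ratios of 1.01 and 0.835. Tenocyte-like shares were 2.66-fold [2.28 to 3.11] and 1.35-fold [1.18 to 1.56] higher, and myogenic-like shares 1.44-fold [1.22 to 1.71] and 1.54-fold [1.33 to 1.79] lower.

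**Figure D2:**
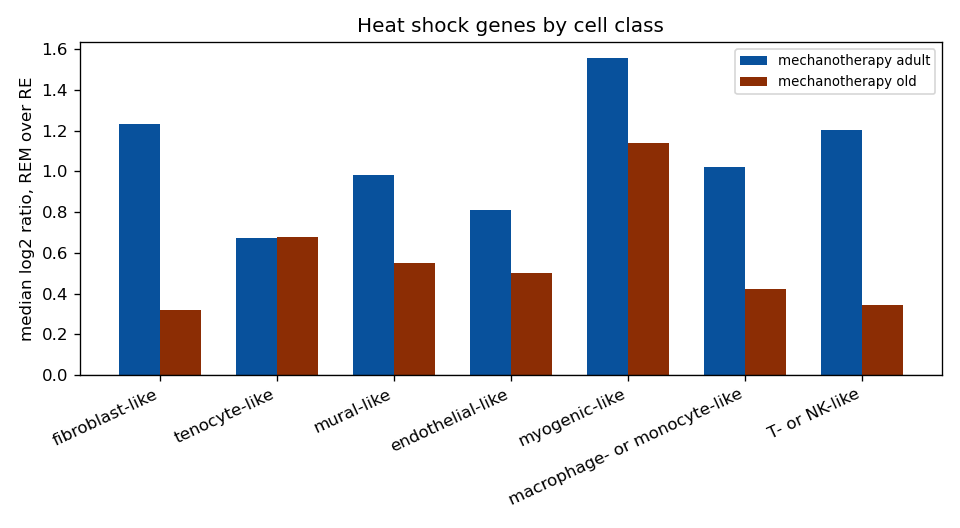
Median log2 ratio of the heat shock list, mechanotherapy over recovery library and not relative to the median of all genes, in each of the 7 classes for adult and old rats (bars; no error is drawn, as each group was 1 library). All 14 medians lie above 0, the adult myogenic-like one at 1.55 and the old fibroblast-like one at 0.32.

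Macrophage-like cells carried more transcripts of several lipid-handling and repair genes with mechanotherapy at both ages. Spp1 (ENSRNOG00000043451), osteopontin, was 5.13-fold [4.36 to 6.08] higher in the adult and 8.74-fold [7.53 to 10.2] in the old mechanotherapy library. The lipid-handling and repair macrophage list had 8 of 16 higher and 0 lower in adult and 8 of 16 higher and 2 lower in old cells. Hmox1 (ENSRNOG00000014117), haem oxygenase, and Lpl (ENSRNOG00000012181), lipoprotein lipase, were 2.33-fold [2.26 to 2.41] and 2.41-fold [2.01 to 2.92] higher in the adult library. Gpnmb (ENSRNOG00000008816), a lysosomal glycoprotein, was 6.27-fold [5.66 to 6.98] and Trem2 (ENSRNOG00000013578), a lipid receptor, 3.14-fold [2.77 to 3.57] higher in the old one, where Hmox1 was 2.76-fold [2.69 to 2.84] lower. Interferon-induced genes were lower in the old mechanotherapy library: Rsad2 (ENSRNOG00000007539) by 25.1-fold [10.4 to 78.8], Ifit2 (ENSRNOG00000036604) by 5.80-fold [4.20 to 8.17] and the chemokine gene Cxcl10 (ENSRNOG00000022256) by 8.75-fold [7.73 to 9.94]. The interferon response list had 0 of 17 higher and 9 lower. In adult cells that list had 2 of 17 higher and 0 lower. The inflammatory macrophage list had 2 of 16 higher and 7 lower in old cells, with Tnf (ENSRNOG00000000837) 5.54-fold [3.36 to 9.61] and Ccl4 (ENSRNOG00000011406) 2.62-fold [2.54 to 2.70] lower, and 3 of 17 higher and 5 lower in adult cells. Also higher in adult cells were Vcan, at 5.10-fold [4.01 to 6.57], NEWGENE_2134 (ENSRNOG00000018426) at 14.8-fold [5.61 to 55.3] and Apoc4 (ENSRNOG00000018405), an apolipoprotein, at least 10.7-fold in 5 cells. Lower were the transcription factor Creb5 (ENSRNOG00000008622) (4.06-fold [3.29 to 5.02]), the splicing factor Srsf5 (ENSRNOG00000005513) (3.26-fold [2.79 to 3.81]), the cholesterol hydroxylase Ch25h (ENSRNOG00000019141) (3.11-fold [2.66 to 3.64]) and Mal (ENSRNOG00000015445) (2.92-fold [2.46 to 3.48]). In old cells NEWGENE_2134 was 131-fold [35.9 to 1085] and the elastase gene Mmp12 (ENSRNOG00000030187) 28.6-fold [4.77 to 1163] higher, the latter in 6 cells. Nppb (ENSRNOG00000008141), a natriuretic peptide precursor, was at least 16.8-fold lower (6 cells) and the potassium channel gene Kcnk10 (ENSRNOG00000003813) 23.5-fold [6.12 to 201]. Dcn, a fibroblast marker, stood in this class at 285 and 562 CPM in the adult recovery and mechanotherapy libraries. Keeping doublets moved log2 ratios from 2.35 to 1.01 for Vcan (adult). In cells thinned to 1000 UMIs, log2 ratios moved to a bound of −0.43 for Apoc4, from −1.64 to −1.05 for Ch25h, from 3.89 to 3.16 for NEWGENE_2134 (adult), from 2.65 to 2.06 for Gpnmb, from 4.84 to −0.83 for Mmp12, to a bound of −0.66 for Nppb, from −4.56 to −0.25 for Kcnk10 and from 7.03 to 4.61 for NEWGENE_2134 (old). The macrophage-like share was 1.41-fold [1.30 to 1.54] higher in the adult mechanotherapy library and 1.24-fold [1.10 to 1.40] lower in the old one, where its ratio was 1.003 with at least 1000 UMIs per cell.

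Lpl, Tcf15 and Gpihbp1, known from capillaries, were lower in endothelial-like cells with mechanotherapy at both ages. Lpl was 2.25-fold [2.04 to 2.48] and 1.56-fold [1.42 to 1.71] lower in adult and old cells, the transcription factor Tcf15 (ENSRNOG00000000012) 2.06-fold [1.87 to 2.28] and 1.73-fold [1.52 to 1.97], and Gpihbp1 (ENSRNOG00000007475), which anchors lipoprotein lipase, 1.88-fold [1.70 to 2.09] and 1.58-fold [1.42 to 1.74]. The endothelial lipid and capillary list had 0 of 9 higher and 4 lower in adult and 0 of 9 higher and 4 lower in old cells. In adult cells Vcam1 (ENSRNOG00000014333) was 5.27-fold [4.07 to 6.92] and Icam1 (ENSRNOG00000020679) 3.49-fold [2.85 to 4.32] higher, both known as adhesion molecules for leukocytes. The endothelial angiogenic and tip cell list had 8 of 19 higher and 0 lower, against 1 of 19 higher and 0 lower in old cells. A cluster led by Selp and Plvap (cluster 21) held 6.09% and 16.5% of this class in the adult recovery and mechanotherapy libraries and 18.6% and 37.2% in the old ones. In adult cells Olr1 (ENSRNOG00000056219), a receptor of oxidised lipoprotein, was at least 46.0-fold higher (12 cells), Inhba (ENSRNOG00000014320), an activin subunit, at least 8.74-fold and Bdnf at least 8.49-fold. The antiviral gene Oas1a (ENSRNOG00000001369) was 2.82-fold [2.21 to 3.63] lower. In old cells the antimicrobial lectin genes Reg3g (ENSRNOG00000006579) and Reg3b (ENSRNOG00000006151) were at least 44.9-fold and 14.9-fold [4.00 to 125] higher, Reg3b in 4 cells. Csf3 (ENSRNOG00000008525), a granulocyte growth factor, was 3.56-fold [3.11 to 4.08] higher. Olr1 was 2.73-fold [2.25 to 3.32] lower, the interferon-induced Gbp5 (ENSRNOG00000032240) 3.23-fold [1.92 to 5.42] and Plekhg2 (ENSRNOG00000030266) 3.05-fold [1.90 to 4.89]. After thinning to 1000 UMIs per cell, log2 ratios moved to a bound of 2.70 for Olr1, to a bound of 0.53 for Inhba, to a bound of 0.85 for Bdnf (adult), to a bound of 3.40 for Reg3g and from 3.89 to 1.08 for Reg3b (old). At most 10% mitochondrial UMIs per cell moved log2 ratios from −1.69 to −0.91 for Gbp5 (old). The endothelial-like share was 1.91-fold [1.71 to 2.13] higher in the old mechanotherapy library and 1.15-fold [1.02 to 1.29] higher in the adult one, where the ratio was 0.935 among cells that were not myofibre-like and 0.908 with at least 1000 UMIs per cell. Myogenic-like cells of the old mechanotherapy library held more Myog (ENSRNOG00000030743), a differentiation factor (28.3-fold [13.5 to 71.4]), and cardiac actin Actc1 (ENSRNOG00000008536) (23.2-fold [6.05 to 198]). The myogenic activation and differentiation list had 6 of 10 higher and 1 lower in old and 1 of 12 higher and 5 lower in adult cells. Outside this class the same list had 3 of 9 higher and 0 lower in fibroblast-like, 3 of 5 higher and 0 lower in macrophage-like and 2 of 5 higher and 0 lower in endothelial-like cells of old rats. In adult rats the counts were 0 of 8 higher and 3 lower, 0 of 7 higher and 3 lower and 0 of 8 higher and 2 lower. Muscle actin Acta1 (ENSRNOG00000017786) stood at 425 and 1065 CPM in macrophage-like cells of the old recovery and mechanotherapy libraries. In their myofibre-like droplets it stood at 115100 and 92700 CPM.

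Sums of ligand and receptor log2 ratios, which do not measure communication, covered 87 pairs fixed beforehand. The largest higher sums of mechanotherapy in adult rats were Col1a1 with Cd44 from mural-like to mural-like (4.88) and to myogenic-like cells (4.50), Mdk with Ncl from mural-like to myogenic-like cells (4.43), and Col1a1 with Itga11 from mural-like to tenocyte-like (4.37) and with Cd44 to macrophage-like cells (4.34). The lowest were Angptl4 with Sdc4 from myogenic-like to endothelial-like cells (−3.54), Spp1 with Cd44 along the same path (−3.40) and Col1a1 with Sdc4 within endothelial-like cells (−3.16). Next were Inhba with Acvr1b from T- or NK-like to mural-like cells (−3.11) and Spp1 with Itgb1 from myogenic-like to macrophage-like cells (−2.89). Spp1 had 0 UMIs in myogenic-like cells of the adult mechanotherapy library, so both its sums rest on the floor of 3 counts. Few UMIs, mechanotherapy against recovery, stood behind mural-like Mdk (24 against 1) and Acvr1b (3 against 9) and endothelial-like Sdc4 (7 against 22). Mural-like Col1a1 stood at 28.0 and 357 CPM in the adult recovery and mechanotherapy libraries, and fibroblast-like Col1a1 at 2285 and 3047 CPM. With at least 50 CPM of ligand and receptor, the lowest sum was −1.93 in adult and −2.95 in old rats. In old rats all 5 largest higher sums had endothelial-like Col1a1 as ligand, with Ddr1 in myogenic-like (4.32), Itga1 and Cd44 in mural-like (4.20 and 4.10), Itga11 in fibroblast-like (4.20) and Ddr2 in tenocyte-like cells (4.02). The lowest were Inhba with Acvr1b from T- or NK-like to mural-like (−3.77) and to fibroblast-like cells (−3.33), Tnc with Sdc4 from fibroblast-like (−3.43) and Ptn with Sdc4 from T- or NK-like to mural-like cells (−3.42), and Pdgfb with Pdgfrb from macrophage-like to tenocyte-like cells (−3.18). UMIs were few for mural-like Acvr1b (4 against 9), Ptn (8 against 52) and Pdgfb (7 against 44). T- or NK-like cells, the ligand side of 3 of these sums in old and 1 in adult rats, held the fibroblast marker Dcn at 2297 and 954 CPM in the old recovery and mechanotherapy libraries and at 1998 and 1855 CPM in the adult ones. The sums do not separate RNA from other cells. Endothelial-like Col1a1 stood at 10.2 and 142 CPM in these old libraries, against 638 and 1679 CPM in fibroblast-like cells.

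Recovery after disuse was read from the recovery library beside the ambulation library of the same age, on different flow cells. Mitochondrial shares of UMIs were higher in recovery than in ambulation, at 3.83% against 2.22% in adult and 3.67% against 2.03% in old fibroblast-like, 7.72% against 4.43% and 7.29% against 4.57% in macrophage-like, and 5.16% against 3.08% and 6.47% against 3.02% in endothelial-like cells. In adult fibroblast-like cells, several basement membrane genes were higher after recovery, and Col1a1 and Col3a1 lower. Col4a2 (ENSRNOG00000023972), a basement membrane collagen, was 3.60-fold [3.03 to 4.31] higher, Lamc1 (ENSRNOG00000002680), a laminin chain, 1.90-fold [1.80 to 2.002] and Nid1 (ENSRNOG00000002461), nidogen, 1.77-fold [1.70 to 1.84]. The basement membrane list had 8 of 16 higher and 2 lower (median 0.46, percentile 100). With clusters weighted alike 5 members were higher. Col1a1 was 2.10-fold [2.07 to 2.12] and Col3a1 1.73-fold [1.71 to 1.74] lower, in a fibrillar collagens list of 1 of 6 higher and 2 lower (0 and 2 with TMM scaling). Matricellular proteins had 7 of 20 higher and 1 lower, Thbs4 being 7.75-fold [7.34 to 8.18] and Ccn2 (ENSRNOG00000015036), connective tissue growth factor, 1.999-fold [1.90 to 2.11] higher. Both lead cluster 12. Other collagens had 3 of 11 higher and 0 lower, with Col8a1 (ENSRNOG00000039668) 2.40-fold [2.19 to 2.64] higher, and TGF-beta family and targets 7 of 23 higher and 0 lower. Heat shock genes were lower, Hspe1 (ENSRNOG00000051624), a mitochondrial chaperonin, by 4.93-fold [4.45 to 5.48], with 0 of 11 higher and 7 lower in that list. Other genes taken by the naming rule, which leaves out markers, were Fmo2 (ENSRNOG00000003510), a flavin monooxygenase (4.12-fold [3.73 to 4.55]), Socs3 (ENSRNOG00000002946), a cytokine signalling suppressor (3.86-fold [3.39 to 4.42]), Cd274 (ENSRNOG00000016112), an immune checkpoint ligand (3.54-fold [3.26 to 3.85]) and the protocadherin Pcdhga11 (ENSRNOG00000027232) (12.4-fold [3.23 to 106]) on the higher side. On the lower side were Rhd (ENSRNOG00000017130), a blood group antigen (5.63-fold [4.43 to 7.23]), Ptgds (ENSRNOG00000015550), a prostaglandin synthase (8.75-fold [4.25 to 20.3], 6 cells), the chemokine Cxcl6 (ENSRNOG00000002843) (5.00-fold [4.04 to 6.23]) and Zg16b (ENSRNOG00000057127) (4.28-fold [3.73 to 4.92]). MHC class II genes had 5 of 5 higher and 0 lower and myogenic activation and differentiation genes 6 of 7 higher and 0 lower. In fibroblast-like cells Cd74 stood at 13.2 and 46.2 CPM and Acta1 at 340.5 and 1415 CPM in the ambulation and recovery libraries. With fibroblast-like clusters weighted alike, log2 ratios moved from −3.13 to −2.11 for Ptgds. Thinning each cell to 1000 UMIs moved log2 ratios from 3.64 to 1.55 for Pcdhga11. The fibroblast-like share was 1.13-fold [1.09 to 1.18] lower, tenocyte-like 5.08-fold [4.37 to 5.91] lower and myogenic-like 1.74-fold [1.43 to 2.14] higher.

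In old fibroblast-like cells the recovery library held more Cd44, Vcan and Adamts9 transcripts, and less Col1a1 and Col3a1, than the ambulation library. Cd44 was 3.32-fold [3.12 to 3.53] and Vcan 2.51-fold [2.44 to 2.59] higher, Cemip2 (ENSRNOG00000012782), a hyaluronidase, 10.4-fold [8.80 to 12.4], Thbs1 8.38-fold [7.07 to 10.0], Adamts9 9.97-fold [7.40 to 13.7] and Timp1 4.19-fold [4.15 to 4.24]. The hyaluronan and versican list had 5 of 9 higher and 2 lower (6 and 1 with TMM scaling), with 3 higher among members with at least 100 UMIs. Matrix proteases had 7 of 22 higher and 4 lower (10 and 1 with TMM scaling) and integrins and matrix receptors 5 of 22 higher and 5 lower (12 and 2 with TMM scaling). Col1a1 and Col3a1 were 2.18-fold [2.14 to 2.23] and 2.86-fold [2.82 to 2.90] lower, Sparc 3.25-fold [3.20 to 3.30] and Eln 2.83-fold [2.57 to 3.10]. Fibrillar collagens had 1 of 6 higher and 5 lower (1 and 2 with TMM scaling), with 2 lower when clusters were weighted alike. Other collagens had 1 of 12 higher and 4 lower (5 and 2 with TMM scaling) and basement membrane genes 0 of 16 higher and 4 lower (2 and 2 with TMM scaling). Elastic fibre and fibronectin genes had 1 of 15 higher and 6 lower, collagen processing and cross-linking genes 1 of 19 higher and 7 lower (2 and 3 with TMM scaling) and matricellular proteins 4 of 20 higher and 1 lower (11 and 1 with TMM scaling). The median of all genes lay at −0.44, so that the relative median of fibrillar collagens was −0.33 and that of hyaluronan and versican 1.57. Immediate-early genes were lower, Fos by 7.16-fold [7.02 to 7.31], Jun (ENSRNOG00000026293) by 4.76-fold [4.68 to 4.84] and Egr1 (ENSRNOG00000019422) by 3.92-fold [3.87 to 3.98]. Their list had 1 of 19 higher and 11 lower (2 and 9 with TMM scaling), with 7 lower with clusters weighted alike. The circadian repressor Nr1d1 (ENSRNOG00000009329) and the clock output gene Dbp (ENSRNOG00000021027) were 9.96-fold [8.91 to 11.1] and 8.73-fold [8.07 to 9.46] lower, Bend5 (ENSRNOG00000008025) 30.3-fold [9.61 to 153] and Saysd1 (ENSRNOG00000006341) 14.1-fold [6.89 to 32.5]. Il1rl1 was 71.5-fold [27.8 to 263] higher, Tac1 (ENSRNOG00000007374), the substance P precursor, 9.81-fold [7.06 to 14.0], and Igh-6 486-fold [208 to 1498] in 8 cells. Heat shock genes had 6 of 11 higher and 2 lower (8 and 0 with TMM scaling), opposite to adult recovery. When clusters counted alike in both libraries, log2 ratios moved from −2.84 to −0.61 for Fos, from −3.32 to −2.04 for Nr1d1, from −3.13 to −2.02 for Dbp, from 3.38 to 2.69 for Cemip2, from 3.07 to 2.30 for Thbs1 and from −3.82 to −2.31 for Saysd1. Thinned to 1000 UMIs per cell, log2 ratios went from −4.92 to −2.50 for Bend5 and from 6.16 to 4.26 for Il1rl1. With doublets kept, log2 ratios moved from 8.93 to −0.03 for Igh-6. The fibroblast-like share was 1.60-fold [1.54 to 1.67] higher, myogenic-like 2.16-fold [1.80 to 2.61] and tenocyte-like 1.89-fold [1.55 to 2.31], and the myofibre-like share 6.87-fold [6.17 to 7.66] lower. Cluster 0 held most of the fibroblast-like cells of the old recovery library and clusters 12 and 1 the largest parts in old ambulation.

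Resident macrophage genes were higher in adult macrophage-like cells after recovery, including the hyaluronan receptor Lyve1 (ENSRNOG00000026902) at 2.29-fold [2.01 to 2.62] and the haemoglobin scavenger receptor Cd163 (ENSRNOG00000010253) at 2.41-fold [1.99 to 2.95]. That list had 7 of 12 higher and 0 lower, lipid-handling and repair genes 9 of 15 higher and 2 lower and interferon response genes 0 of 16 higher and 11 lower. Spp1 was 45.1-fold [7.98 to 1792] higher, Fnip2 (ENSRNOG00000027833) 6.34-fold [3.48 to 12.9], Socs3 12.5-fold [3.35 to 104] and Lmna (ENSRNOG00000019638), lamin A, 3.64-fold [3.31 to 4.02]. The defensin Defb14 (ENSRNOG00000032304) was 22.4-fold [10.0 to 59.1] lower, Acod1 (ENSRNOG00000009919), which makes itaconate, 14.0-fold [9.20 to 22.1], ficolin gene Fcnb (ENSRNOG00000009342) 10.2-fold [8.55 to 12.3] and Mgst2 (ENSRNOG00000061857) 11.4-fold [6.83 to 19.9]. Cluster 23, 1 of 2 in this class, held 46.6% of it in the adult ambulation and 13.3% in the adult recovery library. In old cells Hmox1 was 8.84-fold [8.27 to 9.44] and thioredoxin reductase Txnrd1 (ENSRNOG00000009088) 6.53-fold [5.23 to 8.26] higher, in an iron and oxidative stress list of 5 of 17 higher and 1 lower. Also higher were Plet1 (ENSRNOG00000024346) (11.4-fold [5.88 to 25.2]) and Nppb (at least 6.67-fold). Fos was 5.94-fold [5.33 to 6.63] lower, Cd84 (ENSRNOG00000022884) 18.0-fold [6.38 to 70.1], Evi2a (ENSRNOG00000022764) 7.78-fold [4.89 to 12.8] and Ubd (ENSRNOG00000000768), a ubiquitin-like modifier, 40.5-fold [13.1 to 203] (3 cells). The immediate-early list had 2 of 19 higher and 14 lower. In endothelial-like cells of the adult recovery library Sele (ENSRNOG00000002723), E-selectin, was 6.83-fold [5.10 to 9.27] and Icam1 4.08-fold [3.25 to 5.13] lower. Cluster 21 held 24.4% of this class in the adult ambulation and 6.09% in the adult recovery library, against 33.2% and 18.6% in the old ones. The chemokine Cxcl11 (ENSRNOG00000022298) and Ubd were at least 26.1-fold and 26.5-fold [10.8 to 84.1] lower. The angiogenic and tip cell list had 0 of 19 higher and 10 lower. Lpl was 3.72-fold [3.16 to 4.41] higher there, Fosb (ENSRNOG00000046667) 3.16-fold [2.77 to 3.62] and Nucb2 (ENSRNOG00000020456) 2.96-fold [2.18 to 4.11]. In old endothelial-like cells Olr1 was 19.8-fold [9.45 to 49.96] and the superoxide dismutase Sod2 (ENSRNOG00000019048) 2.63-fold [2.33 to 2.97] higher. Nr1d1 was 5.93-fold [3.33 to 11.2], Col15a1 (ENSRNOG00000060381) 3.99-fold [2.77 to 5.84] and Fos 2.81-fold [2.55 to 3.10] lower there, and the median of all genes lay at −0.20. In cells thinned to 1000 UMIs, log2 ratios moved from 5.50 to 1.75 for Spp1, from 3.64 to 1.54 for Socs3 (macrophage-like, adult), to a bound of −0.20 for Nppb, from −5.34 to −2.84 for Ubd (macrophage-like, old), to a bound of −2.82 for Cxcl11, from −4.73 to −3.68 for Ubd and from −2.77 to −3.70 for Sele (endothelial-like, adult). Requiring at least 1000 UMIs per cell moved log2 ratios from −4.49 to −3.72 for Defb14 (macrophage-like, adult), from 3.14 to 3.79 for Hmox1, from 3.51 to 1.33 for Plet1, from −4.17 to −1.91 for Cd84 and from −2.96 to −2.16 for Evi2a (macrophage-like, old). Keeping doublets moved log2 ratios from −3.36 to −2.10 for Fcnb, from −3.51 to −2.31 for Mgst2 (macrophage-like, adult) and from 4.31 to 3.36 for Olr1 (endothelial-like, old). Averaging each cell's CPM moved log2 ratios from −2.57 to −1.92 for Fos (macrophage-like, old). Across genes, recovery in adult and old cells had a Pearson r of 0.342 (rho 0.402) in fibroblast-like, 0.344 (rho 0.396) in macrophage-like and 0.204 (rho 0.246) in endothelial-like cells. Both contrasts cross the same pair of flow cells. Macrophage-like shares were 1.76-fold [1.55 to 1.997] higher in the adult and 1.44-fold [1.3 to 1.66] in the old recovery library, endothelial-like ones 1.14-fold [0.992 to 1.32] and 1.51-fold [1.30 to 1.76].

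Age was read from the old beside the adult library of each condition. In ambulation, fibroblast-like cells of the old library held less fibrillar collagen and more Thbs4, Ccn2 and Comp. Col1a1 was 3.44-fold [3.39 to 3.49] and Col3a1 1.92-fold [1.90 to 1.94] lower and Col5a3 (ENSRNOG00000020525) 1.67-fold [1.57 to 1.76], with 0 of 6 higher and 4 lower in the list (median −0.77, percentile 0). Thbs4 was 8.56-fold [8.10 to 9.05] higher, Ccn2 4.24-fold [4.03 to 4.47], Comp (ENSRNOG00000048472), cartilage oligomeric matrix protein, 3.18-fold [2.79 to 3.63], Cilp 4.24-fold [4.10 to 4.38] and Ltbp2 6.37-fold [4.14 to 10.2]. Thbs4, Ccn2 and Cilp lead cluster 12, which held more of this class in the old library. Matricellular proteins had 7 of 20 higher and 2 lower, complement genes 4 of 14 higher and 0 lower, myofibroblast genes 4 of 9 higher and 1 lower and heat shock genes 0 of 11 higher and 7 lower. Of single genes, Ankrd55 (ENSRNOG00000013555) was 13.3-fold [7.17 to 27.2] and the neuropeptide precursor Npw (ENSRNOG00000012390) 5.91-fold [5.01 to 7.01] higher. Pitx1 (ENSRNOG00000011423), a hindlimb transcription factor, was 9.44-fold [3.42 to 36.2], Rspo3 (ENSRNOG00000011568), a Wnt agonist, 4.18-fold [3.34 to 5.29], Tac1 5.05-fold [3.55 to 7.37], keratin gene Krt2 (ENSRNOG00000009563) 5.45-fold [3.14 to 10.1] and Sult1e1 19.6-fold [8.14 to 61.5] (17 cells) lower. After thinning to 1000 UMIs per cell, log2 ratios moved from 3.73 to 4.98 for Ankrd55, from −4.29 to −3.42 for Sult1e1, from −3.24 to −2.25 for Pitx1 and from −2.45 to −3.12 for Krt2. Weighting the fibroblast-like clusters alike moved log2 ratios from 2.56 to 1.09 for Npw, from 2.08 to 1.26 for Cilp and from 2.08 to 1.04 for Ccn2. The fibroblast-like share was 1.31-fold [1.254 to 1.37] lower and that of tenocyte-like cells, of which Thbs4 and Comp are markers, 4.95-fold [4.16 to 5.92].

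Between the recovery libraries, fibrillar collagens were lower in old fibroblast-like cells, and Tnc, Cxcl6, Lif and Il11 higher. Col1a1 was 3.58-fold [3.52 to 3.64] lower, Col3a1 3.18-fold [3.14 to 3.21] and Col5a1 (ENSRNOG00000008749) 3.07-fold [2.82 to 3.36]. Fibrillar collagens had 0 of 6 higher and 5 lower (median −1.11, percentile 0.0300). Also lower were Sparc (3.12-fold [3.08 to 3.17]), Eln (3.53-fold [3.26 to 3.83]) and fibrillin gene Fbn1 (ENSRNOG00000007302) (2.72-fold [2.67 to 2.77]), the last a leading gene of cluster 3. Basement membrane genes had 0 of 16 higher and 10 lower (0 and 4 with TMM scaling), and elastic fibre and fibronectin genes 1 of 15 higher and 6 lower (2 and 4 with TMM scaling). Other collagens had 0 of 12 higher and 5 lower (3 and 3 with TMM scaling) and collagen processing and cross-linking genes 1 of 19 higher and 7 lower (2 and 2 with TMM scaling). Tnc was 12.3-fold [9.9 to 15.5] higher, Thbs1 5.37-fold [4.83 to 5.98], Timp1 3.92-fold [3.89 to 3.95] and Lif (ENSRNOG00000007002), a cytokine, 9.22-fold [4.04 to 25.9]. Matricellular proteins had 7 of 21 higher and 3 lower (12 and 2 with TMM scaling), hyaluronan and versican genes 5 of 9 higher and 2 lower (5 and 1 with TMM scaling) and integrins and matrix receptors 3 of 24 higher and 7 lower (11 and 6 with TMM scaling). Matrix proteases had 6 of 24 higher and 6 lower (7 and 2 with TMM scaling), TGF-beta family and targets 6 of 24 higher and 8 lower (10 and 2 with TMM scaling), mechanoresponsive and YAP/TAZ targets 3 of 20 higher and 5 lower (7 and 2 with TMM scaling) and growth factors and chemokines of stroma 9 of 29 higher and 7 lower (16 and 3 with TMM scaling). Cxcl6 was 20.4-fold [16.9 to 24.7] higher, Il1rl1 18.9-fold [12.9 to 28.9], the cytokine Il11 (ENSRNOG00000017386) 24.0-fold [12.9 to 50.5], Sectm1b (ENSRNOG00000036673) 10.0-fold [7.999 to 12.8] and Igh-6 at least 1449-fold. Fos was 9.18-fold [9.01 to 9.35] lower, Ret (ENSRNOG00000014751), a receptor tyrosine kinase, 13.3-fold [9.85 to 18.2], C1qtnf6 (ENSRNOG00000007300) 7.86-fold [6.27 to 9.96], Dmkn 7.37-fold [5.85 to 9.39] and Nppb 29.4-fold [7.68 to 251] (7 cells). The dissociation and immediate-early list had 1 of 19 higher and 12 lower (3 and 11 with TMM scaling), and 5 lower with clusters weighted alike. Heat shock genes had 7 of 11 higher and 0 lower. MHC class II genes had 0 of 5 higher and 5 lower, with Cd74 at 11.4 CPM in old and 46.2 CPM in adult fibroblast-like cells. Cluster 0 held 54.9% of the old and 2.41% of the adult cells of this class, and the median of all genes lay at −0.42. With fibroblast-like clusters weighted alike, log2 ratios moved from 4.35 to 2.56 for Cxcl6, from 4.24 to 2.36 for Il1rl1, from 4.58 to 3.38 for Il11, from 3.33 to 2.23 for Sectm1b, from −3.73 to −3.04 for Ret, from −3.20 to −0.79 for Fos, from −2.98 to −2.17 for C1qtnf6 and from −2.88 to −1.12 for Dmkn. Thinning each cell to 1000 UMIs moved log2 ratios from −4.88 to −1.98 for Nppb and to a bound of 7.08 for Igh-6. The fibroblast-like share was 1.39-fold [1.34 to 1.44] higher, and its ratio 1.03 among cells that were not myofibre-like.

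**Figure D3:**
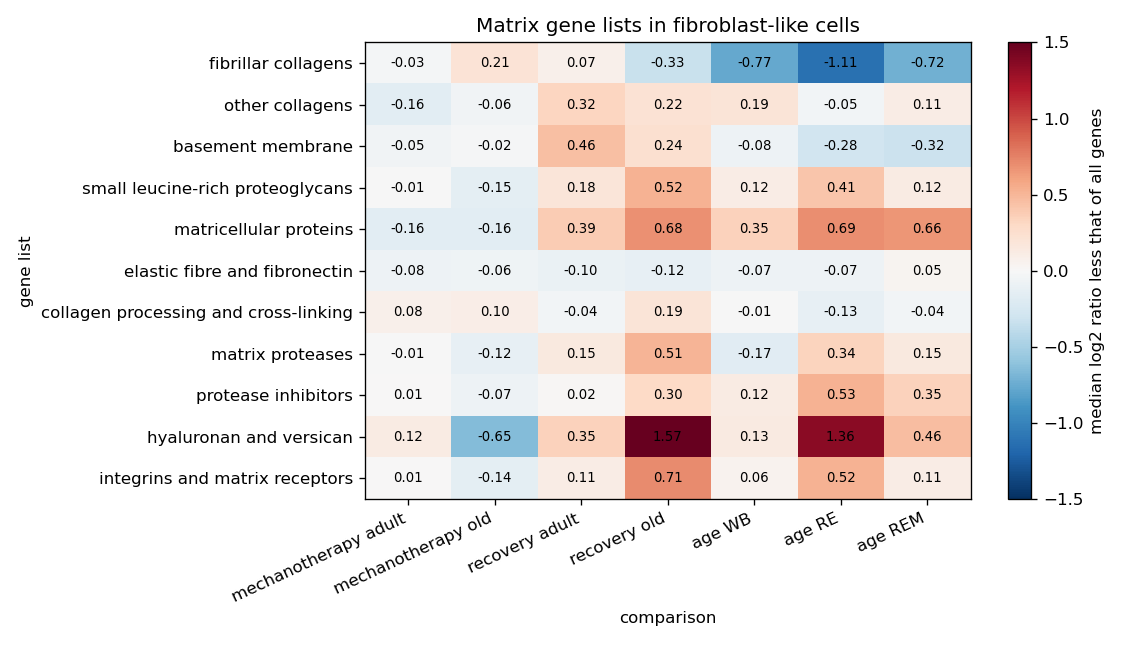
Median log2 ratio of 11 matrix gene lists in fibroblast-like cells, less the median of all genes, for the 7 comparisons (columns; first library over second). Fibrillar collagens reach −1.11 for age in recovery, and hyaluronan and versican genes 1.57 for recovery in old rats.

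Between the mechanotherapy libraries, Col1a1 was 1.81-fold [1.80 to 1.83] and Col3a1 2.45-fold [2.43 to 2.47] lower in old fibroblast-like cells, with 0 of 6 higher and 5 lower in the fibrillar collagens list. Ccn2 was 3.81-fold [3.71 to 3.92] higher and Tnc 3.39-fold [2.71 to 4.27]. The matricellular list had 9 of 20 higher and 1 lower (10 and 0 with TMM scaling), and complement genes had 7 of 15 higher and 2 lower (9 and 1 with TMM scaling). The median of all genes lay at −0.18. Across genes, age in ambulation and in recovery had a Pearson r of 0.125 (rho 0.098) in fibroblast-like, −0.018 (rho −0.044) in macrophage-like and 0.224 (rho 0.24) in endothelial-like cells. In macrophage-like cells of the old ambulation library, MHC class II genes had 6 of 6 higher and 0 lower and interferon response genes 1 of 15 higher and 7 lower. Cluster 8, with RT1-Da and Cd74 among its leading genes, held 71.7% of this class there and 53.4% in the adult ambulation library. Isg15 (ENSRNOG00000021802) was 4.44-fold [3.14 to 6.41] lower, Cxcl10 2.72-fold [2.35 to 3.16] and Slfn4 (ENSRNOG00000057092) 3.23-fold [2.63 to 3.99]. Higher were Spp1 (51.3-fold [8.88 to 2058], 5 cells), the B-cell chemokine Cxcl13 (ENSRNOG00000024899) (4.01-fold [2.19 to 7.93]), Cxcl3 (ENSRNOG00000028043) (2.44-fold [2.12 to 2.80]) and Ubd (at least 14.7-fold, 3 cells). In the old recovery library Rsad2 was 72.4-fold [19.6 to 605], Nppb 58.2-fold [9.92 to 2347], Hmox1 5.36-fold [5.19 to 5.54] and Cxcl3 4.01-fold [3.82 to 4.20] higher in macrophage-like cells. Fos was 7.01-fold [6.37 to 7.74], Atf3 (ENSRNOG00000003745), a stress transcription factor, 5.98-fold [5.34 to 6.70], Egr1 5.39-fold [4.90 to 5.94] and Nr1d1 11.1-fold [4.56 to 35.4] lower. The median of all genes there was −0.10. Endothelial-like cells of the old ambulation library held more Tfpi2 (ENSRNOG00000010513), a protease inhibitor (3.00-fold [2.45 to 3.69]), Tchh (ENSRNOG00000056746) (6.52-fold [2.31 to 25.4]) and the metallothionein Mt1 (ENSRNOG00000038047) (2.62-fold [2.31 to 2.97]). They held less Cxcl11 (6.44-fold [2.99 to 15.9]), Zg16b (4.37-fold [2.48 to 8.16]) and Esm1 (ENSRNOG00000010797), endocan (3.73-fold [2.41 to 5.93]). In recovery, old endothelial-like cells held more Icam1 (5.38-fold [4.39 to 6.63]), Vcam1 (4.91-fold [3.76 to 6.49]), Olr1 (at least 70.3-fold), Ubd (20.1-fold [8.34 to 63.5]) and carboxypeptidase gene Cpe (ENSRNOG00000043387) (18.5-fold [7.61 to 58.2]). They held less Fos (4.36-fold [4.00 to 4.77]), Atf3 (3.07-fold [2.84 to 3.31]) and Calhm5 (ENSRNOG00000000825) (4.58-fold [2.84 to 7.72]). Stromal growth factors and chemokines had 15 of 25 higher and 4 lower. The median of all genes was −0.22, and cluster 21 held 6.09% of adult and 18.6% of old cells. Thinned to 1000 UMIs per cell, log2 ratios went to a bound of 2.24 for Ubd (macrophage-like, ambulation), from 6.18 to 3.58 for Rsad2, from 5.86 to 1.33 for Nppb, from −3.48 to −2.73 for Nr1d1 (macrophage-like, recovery), to a bound of 4.04 for Olr1 and from 4.33 to 3.62 for Ubd (endothelial-like, recovery). In cells with at least 1000 UMIs, log2 ratios moved from 5.68 to 1.53 for Spp1 (macrophage-like, ambulation). With each cell's CPM averaged, log2 ratios moved from 2.003 to 1.12 for Cxcl13 (macrophage-like, ambulation), from 2.70 to 1.23 for Tchh (endothelial-like, ambulation) and from −2.20 to −1.56 for Calhm5 (endothelial-like, recovery). With doublets kept, log2 ratios moved from 1.28 to 0.65 for Cxcl3 (macrophage-like, ambulation) and from −2.69 to −1.81 for Cxcl11 (endothelial-like, ambulation). A limit of 10% mitochondrial UMIs moved log2 ratios from 4.21 to 2.89 for Cpe (endothelial-like, recovery). The macrophage-like share was 2.30-fold [2.08 to 2.54] lower and the endothelial-like share 1.96-fold [1.78 to 2.17] higher in the old mechanotherapy library. In recovery they were 1.31-fold [1.17 to 1.46] lower and 1.18-fold [1.04 to 1.34] higher, the latter with a ratio of 0.875 among cells that were not myofibre-like.

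**Figure D4:**
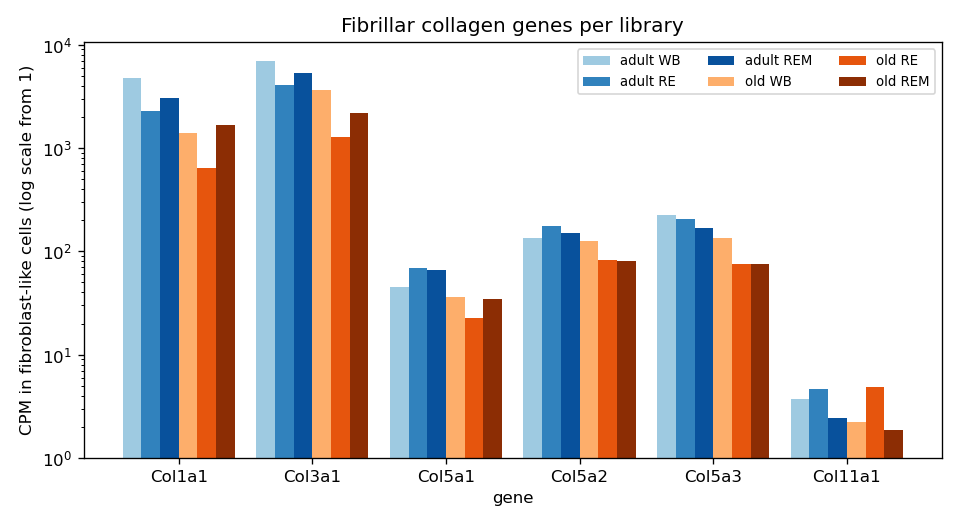
CPM (log axis from 1) of 6 fibrillar collagen genes in fibroblast-like cells of the 6 libraries, 1 bar per library, without error bars as each group was 1 library. Col1a1 stands at 4792, 2285 and 3047 CPM in the adult ambulation, recovery and mechanotherapy libraries and at 1393, 638 and 1679 CPM in the old ones.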

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

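The tests of handling, of a state of the whole library, of the makeup of clusters and of scaling by total counts were chosen after the results were seen, and so was the size of difference that brought a result into this part. Each group was 1 library, so the differences between ages given here were not tested.

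Heat shock genes were higher in both mechanotherapy libraries. Free RNA from fibroblast-like cells stays open, as only levels were compared, against markers of that class. In T- or NK-like cells of both libraries, heat shock genes had at least 9.08 times the fibroblast markers' share of the fibroblast-like level. Thinning left at least 95% of the median log2 ratio, which bears only on the weight of deep cells. Handling or dissociation of these libraries cannot be told apart from mechanotherapy itself, which stays open, untested. The list lay above the 95th percentile of random lists at both ages in 7 of 7 classes, and each library was made apart. The dissociation and immediate-early list had 0 of 19 higher and 11 lower in adult macrophage-like and 10 of 19 higher and 0 lower in old fibroblast-like cells.

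Immediate-early genes were lower in fibroblast-like cells of the old recovery library than in the adult recovery and old ambulation libraries. After thinning, at least 83.4% of the median log2 ratio was left. As above, this bears on the weight of deep cells and cannot decide on depth otherwise. The makeup of fibroblast-like clusters cannot be told apart from a difference within clusters, since 24.0% of the ratio was left in 1 comparison and 59.2% in the other with clusters weighted alike, and Fos itself leads cluster 4. A state of the whole library could account for part of it: the list lay below the 5th percentile of random lists in 4 of 6 other classes in both comparisons. Age and recovery stay open, untested.

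Fibrillar collagens were lower in old than in adult fibroblast-like cells in all 3 conditions. Scaling by total counts was argued against as the whole cause, since at least 74.0% of the median log2 ratio was left with TMM scaling. The makeup of fibroblast-like clusters was argued against likewise, with at least 72.4% left when clusters were weighted alike. Age is a candidate explanation that stays untested, as does the lane in recovery and mechanotherapy.

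Several values had opposite directions in adult and old rats. With mechanotherapy, the fibroblast-like share was 1.247-fold higher in adult and 1.42-fold lower in old rats, the macrophage-like share 1.41-fold higher and 1.24-fold lower, and the myofibre-like share 2.28-fold lower and 4.78-fold higher. The opposition was lost for macrophage-like cells with at least 1000 UMIs per cell, where the old ratio was 1.003, and the adult fibroblast-like ratio was 1.015 among cells that were not myofibre-like. With recovery, the fibroblast-like share was 1.13-fold lower in adult and 1.60-fold higher in old rats, with an adult ratio of 0.9782 among cells that were not myofibre-like, the tenocyte-like share 5.08-fold lower and 1.89-fold higher, and the myofibre-like share 1.37-fold higher and 6.87-fold lower.

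List medians in this part are not relative to the median of all genes. Among them (log2 ratios, adult then old), small leucine-rich proteoglycans in macrophage-like cells stood at 0.98 and −1.37 with mechanotherapy. With recovery, myofibroblast genes in macrophage-like cells stood at 0.83 and −1.45, with 2 of 3 higher and 0 lower in adult and 2 of 5 higher and 3 lower in old cells. In fibroblast-like cells MHC class II genes stood at 2.48 and −0.71 and heat shock genes at −0.86 and 0.60. All genes there had a median of 0.02 in adult and −0.44 in old cells, so that the relative MHC class II median was −0.27 in old cells. Of its 5 members 5 were lower there, but 0 with TMM scaling. Myogenic activation and differentiation genes stood at 2.06 and −1.19 in fibroblast-like, 1.38 and −1.01 in endothelial-like and 0.68 and −1.44 in macrophage-like cells. Fibroblast-like Acta1 stood at 772 and 207 CPM in the old ambulation and recovery libraries, and macrophage-like Dcn at 352, 285 and 562 CPM in the adult and 40.0, 633 and 459 CPM in the old libraries.

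Single genes went apart as well (log2 ratios, adult then old). Values marked as bounds rest on the floor of 3 counts against 0 UMIs. With mechanotherapy these were Il1rl1 at 2.27 and −0.72 and Syce1 at −2.73 and 1.28 in fibroblast-like cells, Olr1 at 5.52 and −1.45 (the adult value a bound) and Reg3g at −3.43 and 5.49 (both bounds) in endothelial-like cells, and Nppb at 4.28 and −4.07 (the old value a bound) and Rsad2 at 2.32 and −4.65 in macrophage-like cells, where adult recovery held 1 UMI of Nppb and 2 of Rsad2 and the counting intervals of the adult values were [1.70 to 9.62] and [0.25 to 5.47]. With recovery they were Cxcl6 at −2.32 and 2.34, Il1rl1 at −1.06 and 6.16 and Tac1 at −2.23 and 3.29 in fibroblast-like cells, Fos at 0.61 and −2.57 in macrophage-like cells, and Olr1 at −1.31 and 4.31 (the adult value a bound) and Fos at 0.64 and −1.49 in endothelial-like cells. Outside the classes compared, the unnamed cluster 24 made up 4.90% of the old mechanotherapy library; Apod, Hbb and Hba-a1 lead it, and its cells' UMI count relative to their library was 0.185.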

How the results depend on the processing

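The alternatives that weight fibroblast-like clusters alike or leave out myofibre-like cells were chosen after the results were seen; the others were planned. Of 3388 alternative gene list counts, 2856 lay within 1.5 times the reported count and 532 moved. Their reversal was not scored, and TMM scaling changed the larger side of some lists. For named genes 917 of 1188 values lay within the counting interval, 267 moved and 4 lay on the other side of 0, 2 as bounds. For share ratios these numbers were 266 of 371, 98 and 7, and for correlations 139 of 168, 24 and 5. Correlations counted as moved from a difference of 0.1 on. Of 4 ligand-receptor values 2 moved. Share ratios are first over second library. With at least 1000 UMIs and 500 genes per cell, the ratio of fibroblast-like shares was 1.15 (mechanotherapy in adult), 0.8361 (mechanotherapy in old), 0.9521 (recovery in adult), 1.541 (recovery in old), 1.237 (age in recovery) and 0.8998 (age in mechanotherapy). Macrophage-like ratios there were 1.268 (mechanotherapy in adult), 1.003 (mechanotherapy in old), 1.486 (recovery in adult), 1.052 (recovery in old) and 0.575 (age in mechanotherapy). Endothelial-like ratios there were 0.9077 (mechanotherapy in adult), 2.49 (mechanotherapy in old), 1.225 (recovery in old), 0.888 (age in recovery) and 2.436 (age in mechanotherapy). The myofibre-like ratio there was 0.9981 (age in mechanotherapy). Among cells that were not myofibre-like, the ratio of fibroblast-like shares was 1.015 (mechanotherapy in adult), 0.8348 (mechanotherapy in old), 0.9782 (recovery in adult), 1.21 (recovery in old), 0.8327 (age in ambulation), 1.03 (age in recovery) and 0.8471 (age in mechanotherapy). Macrophage-like ratios there were 1.15 (mechanotherapy in adult), 0.9561 (mechanotherapy in old), 1.086 (recovery in old) and 0.566 (age in recovery). Endothelial-like ratios there were 0.9352 (mechanotherapy in adult), 2.266 (mechanotherapy in old), 1.139 (recovery in old) and 0.8753 (age in recovery). With doublets kept, the ratio of fibroblast-like shares was 0.8424 (recovery in adult) and 1.495 (age in recovery). With at most 10% mitochondrial UMIs, the ratio of fibroblast-like shares was 0.9173 (recovery in adult). Macrophage-like ratios there were 1.575 (mechanotherapy in adult), 1.398 (recovery in adult) and 0.8697 (age in recovery). Endothelial-like ratios there were 0.9817 (age in recovery) and 1.729 (age in mechanotherapy). Among cells that were not immune- or erythroid-like, the ratio of fibroblast-like shares was 0.6689 (mechanotherapy in old), 0.8198 (age in ambulation) and 0.7508 (age in mechanotherapy). With 1000 variable genes and 20 components, the ratio of fibroblast-like shares was 1.329 (age in recovery). The endothelial-like ratio there was 1.7 (age in mechanotherapy). At resolution 0.5, the ratio of endothelial-like shares was 1.729 (age in mechanotherapy). The direction reversed for macrophage-like shares of mechanotherapy in old rats and for endothelial-like shares of mechanotherapy in adult rats and age in recovery under the settings named, and for myofibre-like shares of age in mechanotherapy.

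After thinning to 1000 UMIs, log2 ratios were −0.43 for Apoc4 (mechanotherapy in adult), −0.83 for Mmp12 (mechanotherapy in old, with 1 UMI in recovery) and −0.20 for Nppb (recovery in old macrophage-like cells). Apoc4 and Nppb had 0 UMIs in 1 library, so their values are bounds and show no change of direction. With doublets kept, Igh-6 reversed to −0.02982 (recovery in old fibroblast-like cells). With clusters weighted alike, members in fibroblast-like cells were counted by size alone. Dissociation and immediate-early genes had 4 higher (mechanotherapy in old), 7 lower (recovery in old) and 5 lower (age in recovery). Basement membrane genes had 5 higher (recovery in adult). Fibrillar collagens had 2 lower (recovery in old), where TMM scaling gave 2 lower. Over members with at least 100 UMIs, 3 hyaluronan and versican members were higher (recovery in old). Pearson r across genes of mechanotherapy in adult and old cells was −0.039 with doublets kept, 0.283 with thinned cells and 0.244 over genes with at least 200 UMIs in endothelial-like cells, 0.33 with at most 10% mitochondrial UMIs and 0.32 over at least 200 UMIs in macrophage-like cells, 0.009 with thinned cells in myogenic-like cells, and −0.03 with doublets kept and −0.009 with each cell's CPM averaged in T- or NK-like cells. For age in ambulation and recovery it was −0.024 in mural-like cells with doublets kept. At 50 CPM, the lowest ligand-receptor sum was −1.933 in adult and −2.95 in old rats. The cause of these shifts was not tested. Depth limits genes with few UMIs most, and thinning leaves them with fewer still. No fit pairing the ages by condition was made, and each group was 1 library.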

Other observations

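Clock genes differed between libraries in fibroblast-like cells. Nr1d1 stood at 96.4, 66.4 and 41.3 CPM in the adult ambulation, recovery and mechanotherapy libraries and at 118, 11.8 and 25.4 CPM in the old ones. Dbp stood at 85.1, 95.3 and 72.3 CPM in the adult and 208, 23.8 and 61.1 CPM in the old libraries. The time of day at which tissue was taken is not given in the sources used here.

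Glycolysis genes had 5 of 14 higher and 0 lower in adult and 4 of 13 higher and 2 lower (6 and 1 with TMM scaling) in old fibroblast-like cells of recovery over ambulation; in old cells the glucose transporter Slc2a1 (ENSRNOG00000007284) was 4.14-fold [3.33 to 5.21] and lactate dehydrogenase gene Ldha (ENSRNOG00000013009) 1.89-fold [1.83 to 1.95] higher. Iron and oxidative stress genes in macrophage-like cells had 2 of 17 higher and 7 lower for mechanotherapy in old rats and 6 of 17 higher and 0 lower for age in recovery, where Nqo1 (ENSRNOG00000012772), a quinone oxidoreductase, was 3.03-fold [2.56 to 3.59] and Gpx3 (ENSRNOG00000052564), a glutathione peroxidase, 3.11-fold [2.61 to 3.73] higher. In fibroblast-like cells, senescence genes had 3 of 12 higher and 5 lower for age in ambulation, protease inhibitors 1 of 10 higher and 2 lower (3 and 2 with TMM scaling) for age in recovery, with Timp4 (ENSRNOG00000007955) 3.60-fold [3.09 to 4.20] lower, and fibro-adipogenic subset and adipogenesis genes 2 of 17 higher and 5 lower (6 and 3 with TMM scaling). Cell cycle genes had 0 of 12 higher and 6 lower (1 and 2 with TMM scaling) and oxidative phosphorylation, nuclear genes 1 of 15 higher and 5 lower (2 and 0 with TMM scaling) for recovery in old fibroblast-like cells. In myogenic-like cells, satellite cell quiescence genes had 2 of 13 higher and 4 lower for age in recovery, where the stem cell factor Pax7 (ENSRNOG00000018739), also a marker of the class, was 4.49-fold [2.91 to 7.16] lower, and 1 of 13 higher and 3 lower for mechanotherapy in adult rats.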
